A study of Mus musculus with 6 samples.

How the data were processed

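The samples were 6 arrays of total RNA from sorted mouse Treg, 3 from the mesenteric lymph node (MLN Treg) and 3 from the colon lamina propria (cLP Treg). Groups were taken from the source label of each sample, since the titles of the MLN samples carry another abbreviation (MSN). Nothing in the labels says whether the samples of a group came from separate animals, so p-values measure only the spread between these samples. Chip and scan are not given in the sources used here, so no batch was fitted.

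The table of non-normalised values that the authors deposited holds the intensity of each probe per array on a linear scale, produced with GenomeStudio 1.6.0 per the submitters' processing notes. A second column per array, headed as a detection p-value, rises with the signal (rank correlation at least 0.991), so it was read as the fraction of negative controls dimmer than the probe, and the detection p was taken as 1 minus this deposited fraction. The deposited series matrix holds log2 values, and comparison with the intensities showed each to be the log2 signal minus the log2 of that array's 75th percentile, with no centring of genes. Every probe matched between the tables by its values on all 6 arrays within a tolerance of 0.1 in signal, with a largest difference of 0.035, so neither scale, centring nor direction stayed unknown. Column medians of the series matrix were -0.728, -0.607 and -0.848 for MLN samples 1 to 3 and -0.596, -0.689 and -0.661 for cLP samples 1 to 3.

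Gene symbols came from the platform annotation, in which 34885 probes had 1 symbol, 18 had several and 10378 had none, giving 19057 genes. Identifiers of 34807 probes were found in the gene table used, and 0 symbols needed an update. Probes with several symbols or none were left out of the gene tests. No probe was named for Il1rl1 or Areg in the annotation used, so these genes are not analysed here.

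Values were analysed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with control moments inferred from the detection p and an offset of 16, followed by quantile normalisation (the neqc method). Probes were kept where the detection p was under 0.05 on at least 3 of the 6 arrays. This left 16215 probes, 13538 of them named, and for each of 9157 genes the probe with the highest mean was tested. Among 1113 genes past the threshold with several such probes, 834 had all probes of the same sign and 80 had a probe past the threshold in the opposite direction. Signal over background is the median signal of detected probes over that of undetected probes. Differences are cLP Treg minus MLN Treg on the log2 scale, from lmFit and eBayes without a block, with their standard error, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Where a gene's reported probe was detected on no array of a group, the fold is given as "at least", from the brighter group's mean against, per array of the dimmer group, the higher of the lowest signal among detected probes and the probe's own value. Where only some arrays of the dimmer group detected it, the fitted difference is given although part of that group's mean is background. In the MLN samples this holds for Ccr2, Hif1a, Hspa1a, Il17a, Kit and Vdr (detected on 1 array) and for Cxcl2, Eprs, Gcnt2, Hdc, Igfbp7, Il18rap, Lgals3, Rora and Top2a (on 2). In the cLP samples it holds for 1600014C10Rik, BC147527, Lyz1, Lyz2 and Zfp94 (on 1) and for Cd160, Egr2, Mx2, Oasl2, Pacs2, Plk1 and Zbtb18 (on 2). Folds given as "at least" are bounds under the main background correction and normalisation only. Unless stated otherwise, for every named gene past the threshold all 3 values of one group lay above all 3 of the other.

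The lists were Treg identity; effector Treg and activation; naive and lymphoid-tissue recirculation; ST2, GATA3 and tissue Treg; chemokine receptors and homing. Further lists covered helper-lineage transcription factors, cytokines, cytokine receptors, the T cell receptor complex and costimulation, the TNF receptor family and NF-kB, immediate early and heat shock genes, the cell cycle, the type I interferon response, glycolysis and hypoxia, lipid and cholesterol metabolism, sensing of xenobiotics, retinoids and microbial metabolites, oxidative phosphorylation, and ribosomal proteins. Marker lists covered cytotoxic and CD8 T cells, conventional helper T cells, innate lymphoid and mast cells, B cells, plasma cells, macrophages with dendritic cells and granulocytes, colon epithelium, stroma with endothelium, erythroid cells, and X inactivation with the Y chromosome. Of 28 lists, 26 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over these lists. With a correlation estimated per list only the effector Treg and helper-lineage transcription factor lists still passed. Lists share members: Il7r, Prdm1, Irf4, Il17a and Ifng among the markers also belong to program lists. Program lists overlap as well. Maf, Batf and Irf4 belong to both the effector Treg and the helper-lineage lists, and Tnfrsf4, Tnfrsf9 and Tnfrsf1b to the effector and TNF receptor lists. Klrg1, Rora, Ccr2 and Dgat2 of the tissue Treg list each belong to another program list. Shifts of such lists are therefore not separate results.

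The lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule named genes the study's question concerns, the 12 largest increases and 12 largest decreases past the threshold whose groups did not overlap, and up to 4 members past the threshold per list with the largest change. Members behind a count of 5 or fewer in a direction that this rule left out, and the members named without passing the threshold, were chosen after their values were seen.

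The steps were tested on simulated data with the real means and spreads of the comparison of 3 against 3 arrays. Of 9157 simulated genes, 200 were changed, 50 per size. The test recovered 0% of those changed by 0.5 on the log2 scale, 16% at 1, 64% at 2 and 94% at 4, with 8 false calls among 95, and the planted list was the only one of 26 called. Simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. Far fewer genes were changed than passed the threshold in the real data (32.5%), so the recovery need not hold there. Alternatives were quantile normalisation without background correction (signals floored at 1), normexp by maximum likelihood with an offset of 50, median scaling, cyclic loess, the series matrix values, 3 other detection filters, the mean of a gene's probes or every probe singly, an intensity trend, array weights, an adjusted p of 0.01, an added 2-fold minimum, the replicate number as a block, camera with an estimated correlation, fry (which tests whether a set moves one way against no change, and does not compare it with other genes as camera does), and the omission of each array in turn. Figures were drawn with matplotlib 3.10.9, with tables read by pandas 2.3.3 and numpy 2.4.6.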

Results

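Gene expression was measured on Illumina bead arrays in regulatory T cells (Treg) of C57BL/6 mice in the steady state, carrying the genotype labelled Foxp3gfp. Cells positive for the T cell receptor beta chain, CD4 and Foxp3 were sorted from the colon lamina propria (cLP Treg, 3 arrays) and from the mesenteric lymph node (MLN Treg, 3 arrays). The share of probes detected was 34.56%, 32.68% and 35.15% in MLN samples 1, 2 and 3, and 35.43%, 34.29% and 35.11% in cLP samples 1, 2 and 3. Signal over background was 3.69, 3.33 and 4.10 in the MLN samples and 2.61, 3.18 and 2.98 in the cLP samples. Across genes, Pearson's r was 0.969 to 0.977 between MLN samples, 0.927 to 0.947 between cLP samples and 0.829 to 0.846 between the groups. Genes are not independent replicates in such a correlation. The median SD of a gene was 0.255 on the log2 scale in the MLN samples and 0.382 in the cLP samples.

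The comparison addressed how the transcripts of Treg in the colonic mucosa differ from those of Treg in a lymph node of the gut. Il10, which encodes an anti-inflammatory cytokine, was 36.7-fold higher in cLP Treg, at a mean log2 intensity of 14.47 ± 0.08 against 9.27 ± 0.04 in MLN Treg (SD, n = 3 each). Klrg1, an inhibitory receptor of differentiated effector lymphocytes, was 16.5-fold higher and Gpr15, a receptor for homing to the large intestine, 6.24-fold higher. Genes of effector Treg, helper-lineage transcription factors, the TNF receptor and NF-kB group, and immediate early and heat shock genes were higher in cLP Treg as groups, and genes of the type I interferon response were lower. With a correlation estimated for each group the effector and transcription factor genes still passed (adjusted p = 0.0422 each), and the other 3 groups did not (adjusted p = 0.0933, 0.167 and 0.295). The measured markers of stromal, plasma, and innate lymphoid and mast cells were higher as sets in the same samples, though not with an estimated correlation (adjusted p = 0.0933, 0.125 and 0.3). Only 6 of 21, 4 of 8 and 3 of 12 such markers named on the array were measured. Foxp3, the transcription factor that defines Treg, had a mean of 13.58 ± 0.26 in cLP Treg and 13.59 ± 0.20 in MLN Treg (SD, n = 3 each).

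Among the genes the comparison was built around, Il10 (probe ILMN_1238505) rose by 5.20 ± 0.20 on the log2 scale (difference ± standard error; limma, adjusted p = 4.85e-05). Klrg1 (ILMN_2944755) rose by 4.04 ± 0.36 (adjusted p = 0.000371) and Gpr15 (ILMN_1217545) by 2.64 ± 0.22 (adjusted p = 0.000286). Ccr7 (ILMN_2821118), the receptor that guides T cells into lymph nodes, was also higher in the colon, by 1.63 ± 0.27 or 3.09-fold (adjusted p = 0.00379). In these 4 genes all 3 cLP values lay above all 3 MLN values. Gata3 (ILMN_1248843), a transcription factor of type 2 helper cells and of a tissue Treg subset, differed by 0.79 ± 0.35 and did not pass the threshold (adjusted p = 0.121; means 9.17 ± 0.35 and 8.37 ± 0.59, SD). Foxp3 (ILMN_2635132) differed by -0.01 ± 0.24 (adjusted p = 0.986), and the sign of its difference changed with the probe and the scaling used.

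Of 9157 genes tested, 2974 (32.5%) passed the threshold, 1110 of them higher and 1864 lower in cLP Treg. Changes of at least 2-fold were seen in 951 of the higher and 1542 of the lower genes, and 3971 genes had an unadjusted p under 0.05. The 3 values of one group lay wholly above those of the other in 4301 genes (47%), where chance gives 10%. The reported probe was not detected on any MLN array for 168 of the higher genes, and on no cLP array for 205 of the lower genes. Higher genes made up 37.3% of the calls, with a median difference over all genes of -0.21. With median scaling they made up 21.5% (831 higher, 3042 lower; median -0.51), in the authors' deposited values 24.1% (882 higher, 2780 lower; median -0.30), and with the median difference set to 0, a setting added after the data were seen, 50.4% (1364 higher, 1342 lower). Without MLN sample 1, 2 or 3 the number of genes past the threshold was 1554 (728 higher, 826 lower), 1664 (883 lower) and 1775 (961 lower), or, with the genes and probes of the full data kept, 1808 (1059 lower), 1910 (1113 lower) and 2049 (1203 lower).

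The largest increase in cLP Treg was in Lmna, which encodes the nuclear lamins A and C and was 110-fold higher. It was followed by Hspa1a, an inducible heat shock protein, at 103-fold, which was detected on 1 MLN array only, with an SD of 1.78 among the MLN samples. Gcnt2, a glycan-branching enzyme, was 66.3-fold higher and the neutrophil chemokine Cxcl2 63.2-fold. Increases were also large in the cell cycle inhibitor Cdkn1a (55.7-fold), the nuclear receptor Rora (52.3-fold) and the tRNA synthetase Eprs (51.7-fold). Gcnt2, Cxcl2, Rora and Eprs were detected on 2 MLN arrays. Dgat1, which completes triglyceride synthesis, rose by 5.64 ± 0.29 on the log2 scale. The reported probes of the other 4 genes were not detected on any MLN array. Ramp3, a partner of calcitonin-family receptors, was at least 45.3-fold higher, the ubiquitin ligase Rnf125 at least 40.2-fold, the smooth muscle actin Acta2 at least 33.7-fold and the organic anion transporter Slco2b1 at least 33.3-fold. Other probes of Acta2 were detected in the MLN, and when cLP sample 1, 2 or 3 was left out and another Acta2 probe was reported in its place, the difference was 0.83, 0.93 or 0.95. In the same way Rnf125 rose by 4.32, 4.73 or 5.00 by another probe. Hspa1a (6.69) rose by 7.68 without MLN sample 2 and by 6.03 without MLN sample 3, and Cxcl2 (5.98) by 6.89 and 5.36. Adjusted p-values of these 12 genes ran from 6.17e-05 to 0.0016 (limma).

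Among the largest decreases, Fam78a fell by 4.69 ± 0.24 on the log2 scale (25.9-fold lower in cLP Treg) and Egr2, a transcription factor induced by the T cell receptor, fell by 4.36 ± 0.66 (20.6-fold lower). The zinc finger gene Zbtb18 fell by 4.30 ± 0.47 and its relative Zfp94 fell by 4.22 ± 0.53. The uncharacterised gene 1600014C10Rik fell by 4.35 ± 0.32 and BC147527 fell by 4.10 ± 0.32, and Igfbp4, which binds insulin-like growth factors, fell by 4.01 ± 0.29. Zfp94, 1600014C10Rik and BC147527 were detected on 1 cLP array, and Egr2, Zbtb18 and Pacs2 on 2. For 4 genes the reported probe was not detected on any cLP array. Ampd1, an AMP deaminase, was at least 16.2-fold lower, Tlr7, a sensor of single-stranded RNA, at least 11.1-fold lower, Adam4 at least 10.3-fold lower and Bcas1 at least 10.2-fold lower. The sorting protein gene Pacs2 had a difference of -4.06 with an SD of 2.37 among the cLP samples (adjusted p = 0.0212), and its call ended without MLN sample 1, 2 or 3 (adjusted p = 0.0659, 0.0533 and 0.0758; 0.00295 to 0.0892 over its alternatives). Its difference was -2.93 without cLP sample 1 and -5.32 without cLP sample 2. Without cLP sample 3 the differences of Egr2 and Zfp94 were -3.56 and -4.93. Adjusted p-values of the other 11 genes ran from 6.17e-05 to 0.00295 (limma).

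**Figure D1:**
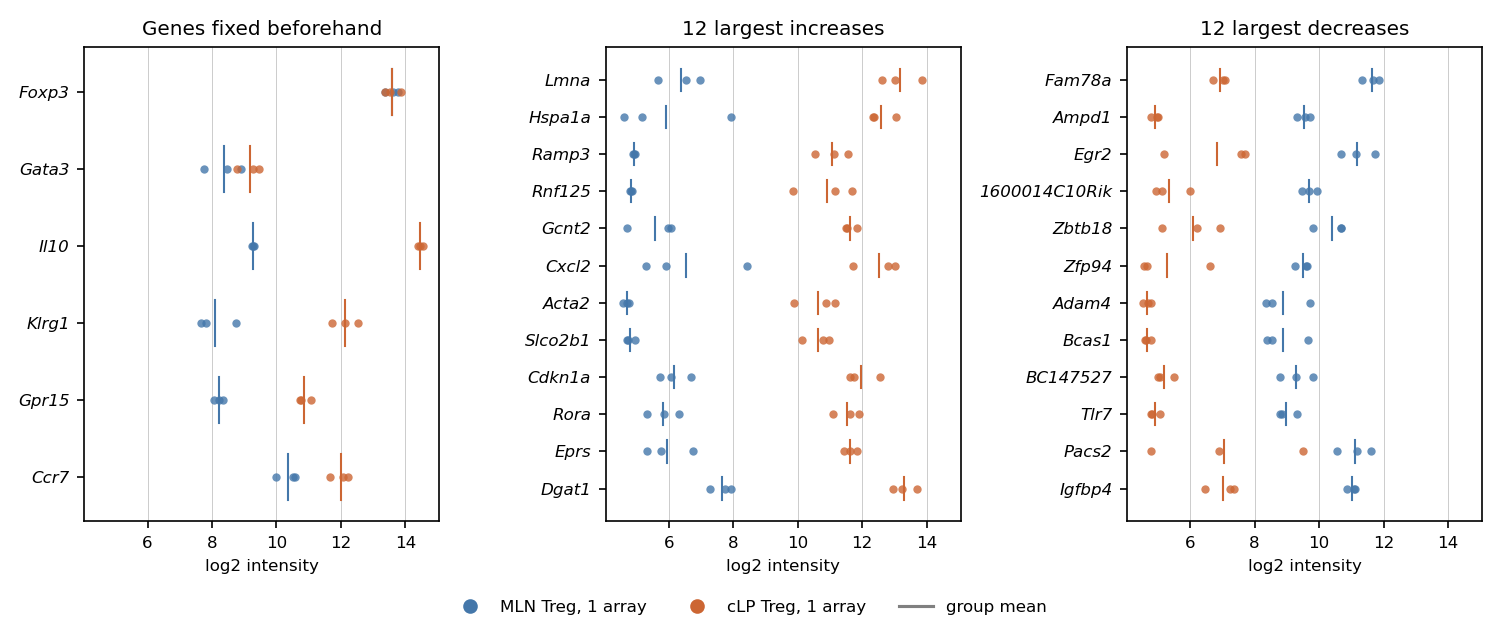
Normalised log2 intensity (x axis) of the genes fixed beforehand and of the 12 largest increases and decreases among genes past the threshold (y axis), with 1 point per array and a bar at each group mean (n = 3 arrays per group). Il10 sits near 14.47 in cLP Treg and 9.27 in MLN Treg, while the Foxp3 values of the groups overlap.

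Genes of Treg identity moved in both directions. Of 14 measured members, 6 were higher and 5 lower in cLP Treg, or 8 and 5 when adjusted over the list alone. Ikzf2, which encodes the transcription factor Helios, rose by 2.22. The orphan receptor Gpr83 fell by 3.02 and the folate receptor family member Izumo1r fell by 2.18. The semaphorin receptor Nrp1 fell by 2.04, the interleukin 2 receptor chain Il2ra fell by 1.67 and the ATP-degrading enzyme Entpd1 fell by 1.59. The set test did not pass (camera, adjusted p = 0.262, direction up), with a list median of 0.78 and a mean of -0.05, which differ in sign. Calls ended for Ikzf2 without MLN sample 1 or 3 (adjusted p = 0.0918 and 0.0874; 0.0147 to 0.092 over its alternatives) and for Nrp1 without MLN sample 2 or 3 (0.0646 and 0.0536; 0.00436 to 0.0646).

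Of 28 measured genes of effector Treg and activation, 21 rose and 1 fell, or 26 and 1 when adjusted over the list alone. Besides Il10 and Klrg1, the largest increases were in Lgals3, which encodes galectin 3 (4.93 ± 0.57), and the inhibitory receptor Havcr2 (4.88 ± 0.35). The integrin chain Itgae, which binds E-cadherin, fell by 1.20 ± 0.24. The activation genes Irf4, Lag3 and Cd44 differed by 0.72, 0.56 and 0.52 without passing the threshold (adjusted p = 0.0647, 0.0867 and 0.0851). All 3 passed without background correction (adjusted p = 0.0412, 0.0423 and 0.0334), Irf4 also without cLP sample 1 (0.0409), and Cd44 also as the mean of its probes (1.26, 0.00275). Over their alternatives the adjusted p ran from 0.0301 to 0.484, 0.0336 to 0.838 and 0.00275 to 0.879. Without MLN sample 1 Lgals3 rose by 4.18. The list was higher as a set (median 1.80, adjusted p = 1.41e-14; adjusted p = 0.0422 with an estimated correlation; 6.81e-21 to 0.0422 over its alternatives). The measured markers of stromal and endothelial cells, of plasma cells, and of innate lymphoid and mast cells were higher as sets in the same samples (adjusted p = 0.000685, 0.0071 and 0.0171; adjusted p = 0.0933, 0.125 and 0.3 with an estimated correlation). These were 6 of 21, 4 of 8 and 3 of 12 markers named on the array.

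Genes of the naive state and of recirculation through lymphoid tissue were split, with 4 of 16 measured members higher and 8 lower, or 4 and 9 when adjusted over the list alone. Igfbp4 fell by 4.01, the actin regulator Evl fell by 3.28 and the actin crosslinker Actn1 fell by 2.64. Id3, an inhibitor of E protein transcription factors, was at least 5.27-fold lower. The 4 that rose were Foxp1, a transcription factor of T cell quiescence (1.96), Ccr7 (1.63), the interleukin 7 receptor Il7r (1.01) and the chromatin organiser Satb1 (0.99). S1pr1, the receptor for exit from lymphoid organs, differed by -0.92 (adjusted p = 0.055). It passed with median scaling (-1.37, adjusted p = 0.00896) and in the authors' deposited values (-1.04, 0.00942), with a range of 0.00896 to 0.15 over its alternatives. The set did not pass by camera (median -0.93, adjusted p = 0.16), but was lower without a detection filter (0.0487) and by fry, which tests against no change (0.00947; 0.00947 to 0.556 over its alternatives). Calls ended for Foxp1 without MLN sample 1 or 3 (adjusted p = 0.0617 and 0.0555; 0.00499 to 0.0617 over its alternatives). They also ended for Il7r without MLN sample 1 or 2 or cLP sample 1 or 2 (0.0956, 0.0806, 0.0595 and 0.0621; 0.00546 to 0.0956) and for Satb1 without MLN sample 1, 2 or 3 or cLP sample 1 or 2 (0.113, 0.0709, 0.0675, 0.0672 and 0.0608; 0.00861 to 0.113).

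In the list of ST2, GATA3 and tissue Treg genes, 5 of 9 measured members rose and 0 fell, over all genes and when adjusted over the list alone alike. Rora rose by 5.71 ± 0.33, the triglyceride synthesis enzyme Dgat2 by 4.06 ± 0.27, Klrg1 by 4.04 ± 0.36, the chemokine receptor Ccr2 by 3.29 ± 0.38 and the opioid precursor Penk by 1.31 ± 0.25. The list was higher as a set (adjusted p = 4.98e-05; adjusted p = 0.0933 with an estimated correlation; 3.46e-06 to 0.0933 over its alternatives), with a median of 1.31. The median was 0.63 without a detection filter, 0.71 in the authors' deposited values, 0.78 without background correction, 0.79 with the stricter filter and 2.30 with detection required in 1 group. It was 2.14 without MLN sample 1 and 2.40 without cLP sample 2. The reported Ccr2 probe was detected on 1 MLN array. Ccr2 was reported by another probe without cLP sample 3, where it differed by 1.07, and under a stricter detection filter, where it differed by 0.74 and its call ended (adjusted p = 0.12; 0.000648 to 0.12 over its alternatives).

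Helper-lineage transcription factors rose as a group, with 11 of 15 measured members higher and 0 lower, or 12 and 0 when adjusted over the list alone. The largest increases after Rora were in Id2, an inhibitor of E protein transcription factors (4.56 ± 0.27), Stat3, which signals for interleukins 6, 10 and 23 (3.92 ± 0.28), and the hypoxia factor Hif1a (3.59 ± 0.31; detected on 1 MLN array). The median was 1.75 and the adjusted p 1.56e-09, or adjusted p = 0.0422 with an estimated correlation (1.02e-10 to 0.0422 over its alternatives).

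Among chemokine receptors and homing molecules, 10 of 20 measured members rose and 5 fell, or 10 and 6 when adjusted over the list alone. Ccr2 rose by 3.29, and Cxcr4, the receptor for the chemokine CXCL12, by 2.85. Ccr8, a receptor of tissue Treg, was at least 5.58-fold higher and the lipid receptor Gpr55 at least 3.83-fold higher, since their probes were not detected on any MLN array. The 5 that fell were the integrin chains Itgb1 (-1.33) and Itgae (-1.20), the follicle-homing receptor Cxcr5 (-1.09), the small intestine homing receptor Ccr9 (at least 1.73-fold lower) and the selectin ligand Selplg (-0.81). The set was higher (median 0.95, adjusted p = 0.0071; adjusted p = 0.11 with an estimated correlation), but not without cLP sample 1, 2 or 3 where the detection filter was applied again (medians 0.27, -0.19 and 0.05; adjusted p = 0.0745, 0.0847 and 0.0976; 0.000124 to 0.142 over all alternatives). The filter needs detection on 3 arrays, so there it removed Ccr8 and Gpr55 whatever their values. The set's median was 0.02 without a detection filter, 0.19 with the stricter one, 0.45 in the authors' deposited values, 0.50 with median scaling, 0.53 without members shared between lists and 0.62 without background correction. Calls of single members ended for Cxcr5 without MLN sample 1, 2 or 3 or cLP sample 1 or 3 (adjusted p = 0.103, 0.0853, 0.104, 0.0809 and 0.0665; 0.00706 to 0.104 over its alternatives). They ended for Selplg without MLN sample 1, 2 or 3 or cLP sample 1 or 2 (0.086, 0.0727, 0.079, 0.0589 and 0.0639; 0.00402 to 0.086) and, with the genes and probes of the full data kept, for Ccr9 without MLN sample 1 or 2 or cLP sample 2 (0.0856, 0.0875 and 0.0678; 0.0149 to 0.152).

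Of 17 measured cytokine genes, 8 rose and 2 fell, or 8 and 3 when adjusted over the list alone. After Il10, the largest increases were in Il17a, the signature cytokine of type 17 helper cells (4.17 ± 0.28; detected on 1 MLN array), and the chemokine Ccl4 (2.53 ± 0.28). Lta and Ltb, which encode the lymphotoxins, differed by -2.40 ± 0.33 and -1.31 ± 0.26, both past the threshold. The set was higher (median 0.62, adjusted p = 0.0071; adjusted p = 0.295 with an estimated correlation). Its median was 0.11 without cLP sample 3, or 0.28 with the genes of the full data kept, and with members shared between lists left out its adjusted p was 0.16 (0.00139 to 0.295 over its alternatives). Its median was 0.21 without a detection filter, and 0.32 to 0.34 without background correction, with the other normexp setting and in the authors' deposited values. Among 28 cytokine receptors, 13 rose and 7 fell, in both adjustments. The interleukin 18 receptor chain Il18rap rose by 4.01 ± 0.24, the interferon gamma receptor chain Ifngr1 by 2.42 ± 0.22 and the interleukin 1 receptor Il1r1 by 2.32 ± 0.37. The interleukin 23 receptor Il23r was at least 2.9-fold higher. The receptor list had a median of 0.42 and was higher as a set (adjusted p = 0.0071; adjusted p = 0.11 with an estimated correlation; 0.000115 to 0.11 over its alternatives). Its median was 0.21 without background correction, 0.24 with the other normexp setting, 0.27 in the authors' deposited values and 0.88 with the stricter filter.

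Of 20 genes of the TNF receptor family and NF-kB, 16 rose and 1 fell, in both adjustments. The NF-kB subunit Rel rose by 4.05 ± 0.39, the NF-kB inhibitor Tnfaip3 by 3.30 ± 0.26 and the adaptor Traf1 by 2.87 ± 0.23, whereas the adaptor Traf2 was at least 8.05-fold lower. The median was 1.67 and the adjusted p 1.32e-09, or adjusted p = 0.0933 with an estimated correlation (1.64e-13 to 0.0933 over its alternatives). Genes of the T cell receptor complex and costimulation did not pass as a set by camera (median -0.39, adjusted p = 0.439) but were lower by fry, which tests against no change and not against other genes (0.0103; 0.0103 to 0.951 over the alternatives), with 2 of 16 higher and 3 lower, or 2 and 4 when adjusted over the list alone. Cd28, the main costimulatory receptor, rose by 2.72 and the adhesion receptor Cd2 by 0.99. The adhesion receptor Cd96 fell by 2.15 and the signalling adaptors Lcp2 and Lat fell as well (-0.97 and -0.90). Cd4 itself differed by -0.07 ± 0.23 (adjusted p = 0.836). Calls ended for Cd2 without MLN sample 2 or 3 or cLP sample 2 (adjusted p = 0.0713, 0.0693 and 0.0525; 0.00417 to 0.0713 over its alternatives). They ended for Lat without MLN sample 1, 2 or 3 (0.0687, 0.075 and 0.0652; 0.00187 to 0.075) and for Lcp2 without MLN sample 1, 2 or 3 or cLP sample 2 (0.0917, 0.051, 0.0668 and 0.0532; 0.00256 to 0.0917).

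All 35 immediate early and heat shock genes were measured, of which 17 rose and 3 fell, or 18 and 3 when adjusted over the list alone. Hspa1a rose by 6.69 ± 0.79, the AP-1 subunit Fosl2 by 5.35 ± 0.24, the heat shock gene Hspa1b by 4.58 ± 0.60 and the zinc finger factor Klf6 by 4.44 ± 0.40. The 3 that fell were Egr2, Egr3 and Egr1, transcription factors induced by the T cell receptor (-4.36, -3.34 and -1.18). The AP-1 genes Fos and Jun differed by 1.17 and -0.63 without passing (adjusted p = 0.214 and 0.253). The set was higher (median 1.17, adjusted p = 1.12e-08; adjusted p = 0.167 with an estimated correlation; 1.46e-10 to 0.167 over its alternatives), with a median of 0.76 with median scaling and 0.77 without cLP sample 2. The call of Egr1 ended without MLN sample 1, 2 or 3 (adjusted p = 0.0866, 0.0555 and 0.0945; 0.00976 to 0.0945 over its alternatives), while Fos passed without MLN sample 2 (0.0268; 0.0251 to 0.536) and Jun without cLP sample 2 (0.0414; 0.0414 to 0.519). Without MLN sample 2 Hspa1a rose by 7.68 and Hspa1b by 5.25, without MLN sample 3 Hspa1a rose by 6.03, and without cLP sample 3 Egr2 differed by -3.56.

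Genes of the type I interferon response were lower in cLP Treg, with 11 of 21 measured members lower and 0 higher in both adjustments. The interferon-induced protease Usp18 fell by 3.44 ± 0.22, and the antiviral genes Ifit2, Oasl2 and Mx2 fell as well (-2.80 ± 0.37, -2.27 ± 0.54 and -1.68 ± 0.34). The set was lower (median -1.02, adjusted p = 0.0171; adjusted p = 0.295 with an estimated correlation), but did not pass without cLP sample 3 where the detection filter was applied again (median -0.74, adjusted p = 0.0552; 0.00225 to 0.295 over its alternatives). Its median was -0.53 in the authors' deposited values, -0.55 without background correction, -0.66 with the other normexp setting and -0.67 without a detection filter. The call of Oasl2 ended without MLN sample 1 or 3 (adjusted p = 0.0667 and 0.053; 0.00771 to 0.0667), and its difference was -1.68 without cLP sample 3.

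Cell cycle genes changed little, with 4 of 27 higher and 1 lower in both adjustments. The centromere histone Cenpa rose by 1.66, the mitotic kinase Cdk1 by 1.58, and the topoisomerase Top2a was 2.83-fold higher. The mitotic kinesin Kif11 was at least 1.75-fold higher, and the mitotic kinase Plk1 fell by 1.36. The set was higher relative to other genes (median 0.21, adjusted p = 0.0492; adjusted p = 0.422 with an estimated correlation), but its median was -0.13 with median scaling, -0.02 in the authors' deposited values and -0.04 without cLP sample 3, against 0.04 without MLN sample 1 and 0.32 without MLN sample 2, and the call ended without MLN sample 1, MLN sample 3 or cLP sample 3 (adjusted p = 0.226, 0.0535 and 0.145; 0.0216 to 0.422 over its alternatives). Single calls ended for Top2a without MLN sample 1 or 2 (adjusted p = 0.0825 and 0.0771; 0.0132 to 0.0825). They ended for Kif11 without MLN sample 2 (0.0611; 0.00808 to 0.0611) and for Plk1 without MLN sample 2 or 3 or cLP sample 2 (0.0898, 0.0747 and 0.0706; 0.0115 to 0.0898).

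Of 17 glycolysis and hypoxia genes, 3 rose and 1 fell in both adjustments. Hif1a rose by 3.59, the hypoxia-induced gene Ndrg1 by 2.96 and the glycolytic enzyme Aldoa by 1.27. Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.26. That set was higher (median 0.44, adjusted p = 0.00788; adjusted p = 0.167 with an estimated correlation; 0.00333 to 0.167 over its alternatives), with a median of 0.10 with median scaling and 0.17 in the authors' deposited values. Of 18 lipid and cholesterol genes, 7 rose and 2 fell, or 7 and 4 when adjusted over the list alone. Dgat1 and Dgat2 rose by 5.64 and 4.06, whereas the cholesterol exporters Abca1, at least 4.95-fold lower, and Abcg1 (-2.01) fell. The lipid set was higher (median 0.65, adjusted p = 0.022; adjusted p = 0.167 with an estimated correlation), with a median of 0.29 without cLP sample 3, 0.22 with median scaling, 0.23 without a detection filter and 0.27 in the authors' deposited values, and an adjusted p of 0.0759 without members shared between lists (0.0035 to 0.167 over its alternatives). The call of Aldoa ended without MLN sample 2 or 3 or cLP sample 2 (adjusted p = 0.0634, 0.0695 and 0.0524; 0.00635 to 0.0849 over its alternatives).

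Oxidative phosphorylation genes did not pass as a set by camera (median -0.20, adjusted p = 0.571). They were lower in the authors' deposited values (median -0.51, adjusted p = 0.0482), where the median of all genes was -0.30. They were also lower by fry (0.0228; 0.0228 to 0.95 over the alternatives), which tests against no change, while their median lay at that of all genes (-0.21). Of 25 measured, 0 rose and 1 fell, Ndufb5, a subunit of complex I (-0.79), or 0 and 0 when adjusted over the list alone, with 3 of them lower at an unadjusted p under 0.05 (limma). None of 27 ribosomal protein genes passed the limma test in either adjustment, and 0 had an unadjusted p under 0.05 (median -0.17, set test adjusted p = 0.943). Both medians turned positive with the median difference set to 0 (0.01 and 0.04) or, for the ribosomal genes, with loess normalisation (0.06). Sensors of xenobiotics, retinoids and microbial metabolites were split, with 2 of 11 higher and 3 lower, or 4 and 3 when adjusted over the list alone. The aryl hydrocarbon receptor target Tiparp was at least 5.11-fold higher and the vitamin D receptor Vdr rose by 1.66. The bacterial peptidoglycan sensor Nod1 fell by 3.64, the retinoic acid receptor Rarg fell by 1.61 and Nod2, a further peptidoglycan sensor, was at least 1.5-fold lower. That set did not pass by camera (adjusted p = 0.846, direction up) and was lower by fry, against no change (0.0276; 0.0276 to 1 over the alternatives), and its median of -0.66 and mean of 0.03 differ in sign. Calls ended for Ndufb5 without MLN sample 1 or 2 or cLP sample 1, 2 or 3 (adjusted p = 0.142, 0.139, 0.063, 0.0705 and 0.0818; 0.00286 to 0.142 over its alternatives) and for Tiparp without MLN sample 1 or 3 (0.0575 and 0.0661; 0.000303 to 0.0732). They ended for Vdr without MLN sample 1 or 2 (0.0668 and 0.0637; 0.0061 to 0.0668) and for Nod2 without cLP sample 1 or 2 (0.0858 and 0.0578; 0.0234 to 0.213). With the genes and probes of the full data kept, Tiparp did not pass without cLP sample 2 either (adjusted p = 0.0521), nor Nod2 without MLN sample 1 or 2 (0.132 and 0.116), and the difference of Tiparp was 4.06 without cLP sample 3.

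**Figure D2:**
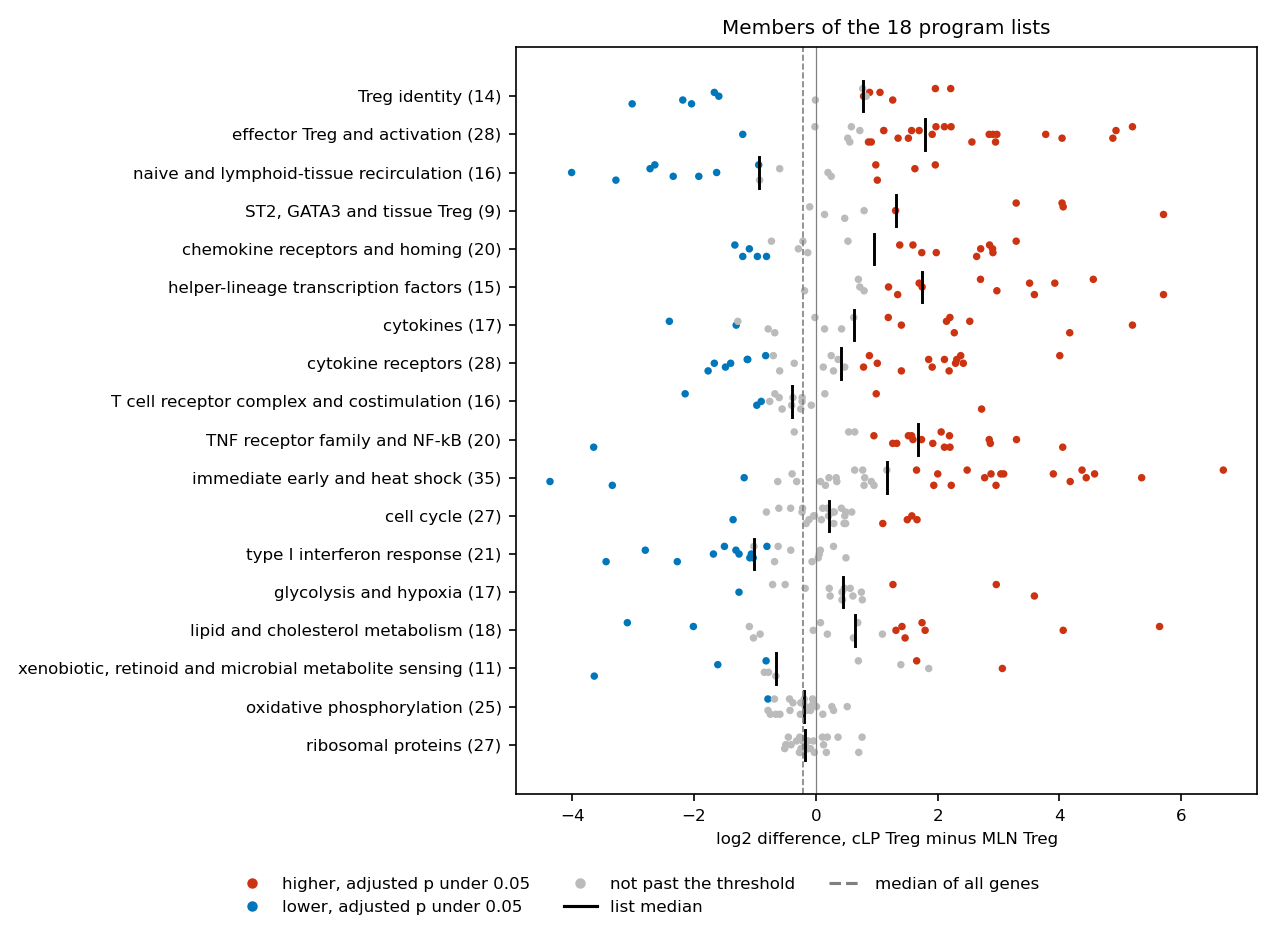
Log2 difference between cLP Treg and MLN Treg (x axis) of each measured member of the fixed gene program lists (y axis, number of measured members in brackets; n = 3 arrays per group), with 1 point per gene, coloured by direction where the adjusted p passed 0.05. Black bars mark list medians and the dashed line the median of all genes (-0.21); the median of effector Treg and activation lies at 1.80 and that of the type I interferon response at -1.02.

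Of 21 stromal and endothelial markers named on the array 6 were measured, of which 4 rose and 0 fell in both adjustments. The reported probes of these 4 were detected on 0 MLN arrays, so they entered the test through the cLP samples, while Col1a1, Lum, Pdgfrb, Cdh5, Lyve1 and Ccl21a were detected on 0 arrays. The reported probe of Acta2 was at least 33.7-fold higher in cLP Treg, the collagens Col3a1 and Col6a1 at least 5.95-fold and 3.45-fold higher, and the matrix protein Sparc at least 1.74-fold higher. The endothelial adhesion molecule Pecam1 differed by -0.11 ± 0.30 (adjusted p = 0.818). The measured stromal set was higher (median 1.95, adjusted p = 0.000685; adjusted p = 0.0933 with an estimated correlation), but did not pass without cLP sample 1, 2 or 3 where the detection filter was applied again (medians 0.46, 0.53 and 0.74; adjusted p = 0.17, 0.285 and 0.128; 7.98e-05 to 0.285 over its alternatives). The filter needs detection on 3 arrays, so there it removed the reported probes of the 4 risen genes whatever their values. The set's median was 0.10 without a detection filter (adjusted p = 0.00374), 0.96 without background correction, 0.97 in the authors' deposited values and 1.15 with the other normexp setting. The call of Sparc ended without MLN sample 1, 2 or 3 (adjusted p = 0.0623, 0.0511 and 0.0586; 0.00366 to 0.0623). Of 23 colon epithelial markers 7 were measured, and 1 rose in both adjustments, Tspan8, a surface tetraspanin (at least 3.89-fold higher). The keratin Krt8 differed by 1.62 ± 0.54 (adjusted p = 0.0544), or 1.04 without cLP sample 3, and passed without cLP sample 1 (2.28, adjusted p = 0.00592; 0.00586 to 0.159 over its alternatives). The epithelial set did not pass (median 0.82, adjusted p = 0.0537). It passed without MLN sample 2 or cLP sample 1 (0.0476 and 0.0344), with median scaling (0.0172) and in the authors' deposited values (0.0247; 0.00647 to 0.397 over its alternatives), and its median was 0.17 without cLP sample 3.

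Lymphoid and myeloid markers did not share a direction. Of 8 plasma cell markers 4 were measured, all higher when adjusted over the list alone and 3 over all genes, with 0 lower, while Sdc1, Tnfrsf17 and Derl3 were detected on 0 arrays. Of the measured 4, Irf4 and Prdm1 also belong to program lists. The immunoglobulin joining chain Jchain was at least 2.13-fold higher, the secretory pathway factor Xbp1 rose by 1.02 and Prdm1, a transcription factor of plasma cells and effector T cells, by 0.87 (set median 0.94, adjusted p = 0.0071; adjusted p = 0.125 with an estimated correlation; 0.00072 to 0.125 over its alternatives). The plasma cell median was 0.51 with median scaling, 0.54 in the authors' deposited values and 0.55 without a detection filter. Of 12 innate lymphoid and mast cell markers 3 were measured, and these rose in both adjustments, the histidine decarboxylase Hdc by 3.27, the stem cell factor receptor Kit by 2.14 and Il7r by 1.01 (adjusted p = 0.0171; adjusted p = 0.3 with an estimated correlation; 0.00589 to 0.3 over its alternatives). The median of this set was 2.14, or 1.06 in the authors' deposited values, 1.16 without background correction and 1.35 with the other normexp setting. Without a detection filter the set did not pass (median 0.03, adjusted p = 0.127), and Cpa3, Mcpt1, Mcpt2, Mcpt4, Fcer1a, Ms4a2, Tpsab1, Tpsb2 and Gata2 were detected on 0 arrays. Of 9 markers of conventional helper cells 2 were measured, Il17a and Ifng, and both rose in both adjustments (4.17 and 2.15), too few for a set test. Of 11 cytotoxic markers 6 were measured, of which 3 rose, the receptor Klrd1 (at least 2.51-fold), the granule gene Nkg7 (1.88) and the perforin gene Prf1 (0.77), and 1 fell, the receptor Cd160 (-1.91), or 3 and 2 when adjusted over the list alone (set median 0.12, adjusted p = 0.414). The CD8 chain Cd8b1 differed by -0.78 (adjusted p = 0.061), and passed without cLP sample 3 (-1.02, adjusted p = 0.0155) and with median scaling (-1.17, 0.0139; 0.013 to 0.17 over its alternatives). The other CD8 chain, Cd8a, was detected on 0 arrays, as were Klrk1, Gzmk, Eomes and Ncr1. Of 10 B cell markers 7 were measured, of which 2 fell, the antigen receptor chain Cd79b (-2.69) and the IgM receptor Fcmr (5.92-fold lower), or 3 fell when adjusted over the list alone, with 0 higher (set median -0.46, adjusted p = 0.098). The B cell set passed without MLN sample 3 (median -1.02, adjusted p = 0.0213, or -0.79 and 0.0333 with the genes and probes of the full data kept), without a detection filter (0.0308), with detection required in 1 group (-1.79, 0.0416) and by fry, against no change (0.012; 0.012 to 0.516 over its alternatives). Of 21 macrophage, dendritic cell and granulocyte markers 5 were measured, of which the lysozymes Lyz1 and Lyz2 fell (-1.84 and -1.53) and Siglech, a marker of plasmacytoid dendritic cells, rose by 1.45 by 1 of its 3 probes, the others lying at background, with the same counts when adjusted over the list alone (adjusted p = 0.934, direction up, against a set median of -0.20 and a mean of -0.36, which differ in sign from the test). No erythroid marker was measured, of 4 named on the array. None of 4 genes of X inactivation and the Y chromosome passed the limma test in either adjustment, and 0 had an unadjusted p under 0.05 (set median 0.34, adjusted p = 0.511), and Xist differed by 1.19 ± 1.07.

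Leaving out an MLN sample lowered the number of calls over all genes. Without MLN sample 1, 2 or 3 the genes past the threshold fell from 2974 to 1554, 1664 and 1775. Without cLP sample 1 or 2 they numbered 2552 and 2364, and without cLP sample 3 they rose to 3067. A call lost without an MLN sample thus does not by itself show that this sample carried it. Several of these single calls ended when 1 sample was left out. For Jchain and Prdm1 they ended without MLN sample 1, 2 or 3 (adjusted p = 0.0845, 0.0594 and 0.0953, and 0.0727, 0.0678 and 0.0601; over their alternatives 0.0167 to 0.0953 and 0.00666 to 0.188), and for Cd160 likewise (0.0677, 0.116 and 0.0776; 0.0122 to 0.116). For Kit the call ended without MLN sample 1 or 2 or cLP sample 1 or 2 (0.0958, 0.0958, 0.0628 and 0.0627; 0.00927 to 0.0974) and for Ifng, whose groups overlapped, without MLN sample 1 or 3 or cLP sample 1 or 3 (0.13, 0.158, 0.0895 and 0.0921; 0.0271 to 0.158). For Prf1 it ended without MLN sample 1, 2 or 3 or cLP sample 1 or 2 (0.122, 0.0622, 0.0694, 0.06 and 0.0621) and with the mean of its probes (0.708; 0.00163 to 0.708). For Lyz1, whose groups overlapped, it ended without MLN sample 1, 2 or 3 or cLP sample 2 or 3 (0.133, 0.14, 0.0574, 0.121 and 0.0941; 0.00534 to 0.141) and for Lyz2 without MLN sample 1 or 2 or cLP sample 2 (0.0807, 0.0752 and 0.058; 0.0131 to 0.0807). Hdc did not pass without a detection filter (0.0592; 0.00754 to 0.0592), and rose by 2.44 without MLN sample 1. The difference of Ifng was 2.75 without cLP sample 2 and 1.54 without cLP sample 3, that of Cd160 -1.32 without cLP sample 2 and that of Lyz1 -2.52 without cLP sample 1.

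**Figure D3:**
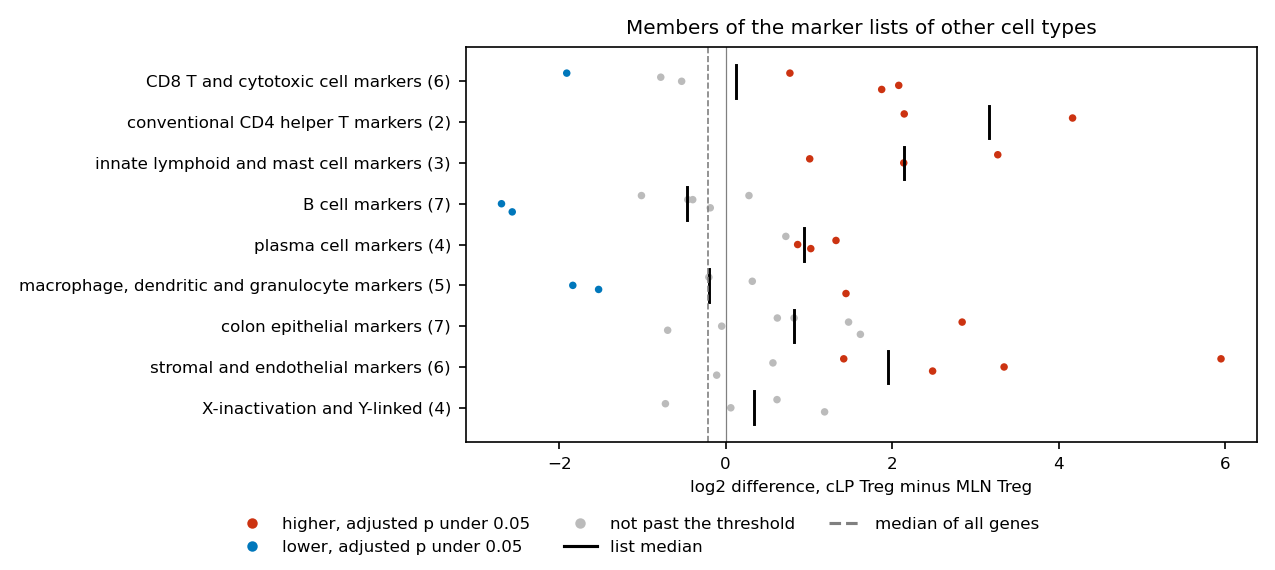
Log2 difference between cLP Treg and MLN Treg (x axis) of each measured member of the marker lists of other cell types (y axis, number of measured members in brackets; n = 3 arrays per group), with 1 point per gene, coloured by direction where the adjusted p passed 0.05. Black bars mark list medians and the dashed line the median of all genes (-0.21); the stromal median lies at 1.95 and that of the B cell markers at -0.46.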

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

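The tests of scaling between arrays were chosen after the results they concern had been seen; the other tests here were written down before. Probes without a gene name lie outside the gene comparison, and 787 of 2677 tested (29.4%) passed the threshold, 456 higher and 331 lower in cLP Treg, against 4379 of 13538 named probes (32.3%). The largest differences were 6.36 ± 0.31 for ILMN_1238547 and -4.23 ± 0.60 for ILMN_1213875 (limma, adjusted p = 6.32e-05 and 0.00248).

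The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2974 genes past the threshold and the highest of the others 0. Every other split mixes both tissues in each group, so the tissue difference adds to the spread and genes could hardly pass. For lists the real split gave 15 past the threshold and the others 4 to 11, while part of the tissue difference remains in those splits. In both cases 1 of the 10 splits, the real one, gave as many. For these reasons the counts do not measure support for the real grouping.

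More genes were lower than higher in cLP Treg. With the median difference of the tested genes set to 0, 50.4% of the genes past the threshold were higher, against 37.3% as reported, but centring by itself moves this share towards an even split and decides nothing. The share was 21.5% with median scaling, 24.1% in the series matrix values and 42.5% with loess. With every probe tested singly it was 45.5%, so it also depended on the choice of probe. Among probes without a gene name more were higher (456) than lower (331). Scaling between arrays and a shift of most transcripts between the tissues cannot be told apart, since the array data hold no external standard.

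The 6 of 21 stromal markers that were measured were higher in cLP Treg as a set, 4 of them with reported probes detected on 0 MLN arrays. The set did not pass with an estimated correlation (adjusted p = 0.0933) or where the filter was applied again without cLP sample 1, 2 or 3 (0.17, 0.285 and 0.128), and its median of 1.95 was 0.10 without a detection filter. Applying the filter again without a cLP sample removes these 4 reported probes whatever their values, so those omissions do not test the shift of the set. RNA of smooth muscle cells or fibroblasts in the sorted samples is a candidate explanation. Of 15 other smooth muscle and fibroblast genes named on the array, 5 (33.3%) were detected on all cLP arrays and higher: Tpm2, Mylk, Bgn and Col4a1 (at least 1.82, 2.42, 2.76 and 1.93-fold) and Igfbp7 (by 3.36 on the log2 scale). The set as first written had 20 genes with 25% higher, and 5 already in the fixed stromal list were left out by rule after it was written. The smooth muscle gene Actg2 was detected on all 6 arrays and did not pass (0.38, adjusted p = 0.719), and 5 genes, among them Tagln and Cnn1 of smooth muscle, were detected on no cLP array. The share lay between the bounds set beforehand, so contaminating RNA and expression in colonic Treg cannot be told apart, although sorting for the T cell receptor, CD4 and Foxp3 should remove such cells.

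Immediate early and heat shock genes were higher in cLP Treg as a set, with 17 of 35 higher, but not with an estimated correlation (adjusted p = 0.167). The list's median stayed positive under each scaling tried. It was lowest at 0.76 with median scaling, which lowers the cLP values most and gave -0.51 for all genes. A shift common to all genes hardly changes the gap between the list and other genes, so this test could not exclude scaling between arrays. Of 19 measured genes of a separate set known to respond to tissue dissociation, 12 (63.2%) were higher and 0 lower, among them Mt1, Myadm, Odc1 and Hspb1 (4.02, 3.23, 3.03 and 3.03), which is consistent with a response to the preparation of the colon. Activation of Treg in the tissue would raise many of the same genes and was not tested, since preparation and tissue go together in this design. Egr1, Egr2 and Egr3, also immediate early genes, were lower.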

How the results depend on the processing

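The setting with the median difference at 0, the lists without shared members and the omission of arrays with the full data's genes and probes kept were added after the data were seen, the last because applying the filter again to 5 arrays drops genes seen in 1 group. Of 117 named genes past the threshold, 84 kept direction and call under each alternative that tested them, but only 58 were tested under all 25, of which 42 kept both; 59 had no value with detection on all 6 arrays. Over 2800 comparisons 2530 were unchanged, 270 lost the call and 0 reversed. Named genes not past the threshold gained a call in 43 comparisons, among Cd44, Cd8b1, Fos, Irf4, Jun, Krt8, Lag3 and S1pr1. For the 26 lists tested, 640 of 720 comparisons were unchanged, 36 lost a call, 21 gained one and 23 changed direction, the last all in 3 lists not past the threshold, and 8 of the 15 lists past the threshold stayed there under each alternative that tested them but the estimated correlation. Of these 8, 6 were tested under all 28 alternatives; the tissue Treg and plasma cell lists had too few members without those shared. The estimated correlation left 2 lists and the lists without shared members 9, with 3 lost and 3 not tested. With detection on all 6 arrays 2 of the 15 were not tested. Lower genes numbered 3042 with median scaling. Every probe tested singly gave 5166 probes past the threshold (2351 higher, 2815 lower), which counts probes in place of genes, and an adjusted p of 0.01 gave 1428 genes (624 higher, 804 lower). Leaving out 1 array gave 1554 to 3067 genes (728 to 1021 higher, 826 to 2046 lower) and 11 to 16 lists, or with the full data's genes and probes kept 1808 to 3223 genes (749 to 1176 higher, 1059 to 2047 lower; without MLN sample 2 1910 genes with 1113 lower, without MLN sample 3 1203 lower) and 14 to 16 lists. Among these omissions, the calls of the stromal, chemokine receptor and interferon lists, and that of the cell cycle list without MLN sample 3 (0.0535), ended only where the filter was applied again. The stricter filter also ended the chemokine receptor call (0.142).

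The set test changed direction for sensing of xenobiotics (median -0.66, lower by fry; -0.02 without a filter, -0.78 with the stricter one, -0.45 with the median at 0, -0.89 to 0.09 without 1 array), ribosomal proteins (0.06 with loess, -0.17 with the block, 0.04 with the median at 0, -0.25 to -0.09 without 1 array, with -0.14 without cLP sample 2) and macrophages with dendritic cells and granulocytes (-0.21 with array weights, -0.20 with the block or fry, -0.24 to -0.16 without 1 array, with -0.18 without cLP sample 1). Medians took both signs over the alternatives in these lists and in those of chemokine receptors (-0.19 to 1.42), the cell cycle (-0.13 to 0.42), oxidative phosphorylation (-0.64 to 0.01) and cytotoxic cells (-0.60 to 0.77).

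Genes not past the threshold that changed sign were Foxp3 (0.24 with loess, 0.21 as the mean of its probes, 0.01 with array weights, 0.20 with the median at 0, -0.15 to 0.10 without 1 array, with 0.09 without MLN sample 2 and 0.03 without cLP sample 3), Cd4 (0.08 with loess, 0.13 with the median at 0, -0.20 to 0.06 without 1 array), Pecam1 (0.21 as the mean of its probes, 0.10 with the median at 0, -0.38 to 0.07 without 1 array, with 0.05 without MLN sample 1) and Xist (-0.10 to 2.07 without 1 array). The cause was not tested. No pairing by replicate number was seen: deviations of same-numbered samples correlated at -0.165, -0.105 and -0.011, and no sample correlated best with its own number. With 3 samples per group this cannot exclude a shared animal, day or batch. With the replicate number as a block 2453 genes passed (937 higher, 1516 lower) and 16 lists. A batch fit was not run, since chip and scan are not given in the sources used here. Signal over background of 2.61 to 4.10 limits what can be said of dim probes. Folds against undetected probes are lower bounds under the main background correction and normalisation only. Without background correction Jchain differed by 0.61 and Nod2 by -0.34 on the log2 scale, against 1.33 and -0.82 in the main fit.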

Other observations

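The values here were looked at after the comparison had been made, and the genes were chosen after their values were seen. Clca1 (ILMN_2690676), a goblet cell gene, had log2 intensities of 9.17, 8.52 and 4.54 in cLP samples 1, 2 and 3, and Muc2 (ILMN_2675214), the main mucin of the colon, 8.74, 8.41 and 5.19, while in the MLN samples these probes lay between 4.62 and 4.86. The other Clca1 probe (ILMN_2690677) had 7.86, 7.63 and 5.58 in the cLP samples and 5.40, 5.69 and 5.56 in the MLN samples, of which 2 were detected. The other 2 Muc2 probes were detected on 0 arrays. The goblet cell genes Tff3, Zg16, Fcgbp and Agr2 were detected on 0 of the cLP arrays. Other epithelial genes did not share an order: Car1 (5.38, 5.96 and 7.80), Krt19 (4.87, 4.63 and 7.62) and Cdh1 (ILMN_2628629; 5.44, 5.74 and 8.42) were highest in cLP sample 3, and Epcam (6.10, 8.16 and 7.34), Krt20 (4.68, 6.07 and 5.17) and Slc26a3 (ILMN_2545805; 5.36, 5.82 and 4.77) in cLP sample 2. Krt8 (ILMN_1221157; 6.67, 7.95 and 9.06), Tspan8 (6.67, 7.31 and 8.59) and each Lgals4 probe were also highest in cLP sample 3. The probes of Krt19, Krt20 and Slc26a3 were detected on 1 cLP array. Epcam (7.65, 8.27 and 7.77) and Cdh1 (5.64, 6.07 and 6.03) were detected on all 3 MLN arrays, so their signal was not particular to the colon. The second principal component, with 13.454% of the variance, separated the cLP samples at 35.0, 9.70 and -47.48.

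Xist, which silences the X chromosome in females, had values of 7.96, 8.93 and 4.58 in MLN samples 1, 2 and 3 and 9.54, 7.95 and 7.54 in the cLP samples by the reported probe (ILMN_2475156), and 8.59, 8.23 and 5.09, and 5.90, 6.16 and 8.92, by another (ILMN_3123341). Both probes were detected on 2 MLN arrays and 3 cLP arrays. The Y-linked Eif2s3y (ILMN_1241001) was detected on all 6 arrays, at 10.55, 10.50 and 11.75 in the MLN samples and 11.98, 11.74 and 10.93 in the cLP samples, so transcripts of both sex chromosomes' genes were seen together in most samples.

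Genes were also grouped by the stem of their symbol into 63 families. With limma's camera test 0 families passed the threshold, and 5 had an unadjusted p under 0.05. The Il stem, 33 genes with 12 higher and 6 lower, came first (adjusted p = 0.21, median 0.29).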
